A study of Macaca mulatta with 83 samples.

How the data were processed

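Whole blood was drawn from female rhesus macaques, and per the labels' protocols 1 mL from each draw was incubated for 4 h at 37 °C with LPS at 1 µg/mL and another 1 mL with medium alone. Red cells were lysed before RNA extraction, and poly(A) RNA was sequenced as single-end reads of 100 bases. The deposited count table holds whole-number read counts per gene symbol that the authors made from these reads, not normalized. Per the submitters' processing notes the tools were Trim Galore 0.2.7, STAR, HTSeq 0.6.1 and limma. Their roles, the genome build, the annotation and the strand setting of the counting are not given in the sources used here. A second deposited table holds residual log2 expression, centred on 0, for a filtered set of genes, and the model behind these residuals is not given in the sources used here. In that table the largest median absolute mean of a study group was 0.02, against at least 0.10 in log2 CPM from the counts, so differences between study groups over both treatments together are nearly absent from it. Differences in the response are not, with 285 genes by limma. Its differences between LPS and control had r = 0.998, across genes, with those of log2 CPM. The residuals served only as an alternative input.

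The count table has 16049 genes, and 9047 genes are in the residual table. All columns matched a sample by name. Of the 16049 symbols, 14436 were found in a table of gene names or of RefSeq genes for this species. No reference genome was used, so no coordinates are given. Reads of near-identical copies and of overlapping genes may be shared, and the values of such genes are uncertain.

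Libraries were grouped by the treatment, study group, animal and sample date in the labels. Of 44 animals 39 had both libraries, 4 a control library only and 1 an LPS library only. Replicates are separate animals. For 3 animals the labels give different sample dates to the 2 libraries. The labels state that both tubes came from 1 draw, which pairs the libraries. As a check, the correlation of the deviations from the treatment means within a pair had a median of 0.577 and ran from 0.203 to 0.846, and 39 of 39 pairs were above 0.1. For 27 of 39 control libraries the best match among the LPS libraries was that of the same animal. No 2 libraries were identical. Dominance rank was not analysed here.

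Tests used edgeR 4.0.16 in R 4.3.3, with limma 3.58.1 and DESeq2 1.42.0 for alternatives. Genes were kept by filterByExpr, libraries were scaled by TMM, and robust quasi-likelihood F tests were adjusted by the Benjamini-Hochberg method at 0.05. The LPS response was fitted on the 39 pairs with the animal as a block, and its standard error was taken from the fold change and the F statistic. Study groups were compared in the control libraries, in the LPS libraries, and in the response as the interaction of study group and treatment with the animal as a block. Printed CPM used the TMM library sizes, and log2 CPM a prior count of 2.

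Gene lists were tested with camera in limma on voom values, two-sided, with an estimated correlation between genes and Benjamini-Hochberg adjustment over 23 lists. The 14 pathway lists were inflammatory cytokines, chemokines, NF-kB pathway and feedback, interferon-stimulated genes, TLR4 receptor complex and adaptors, immediate early and AP-1, inflammasome, glucocorticoid-responsive, glycolysis, oxidative phosphorylation, MHC class II presentation, MHC class I presentation, phagocyte receptors and ribosomal proteins. The 9 cell type lists were neutrophil, monocyte, B cell, T cell, cytotoxic and NK, platelet, erythroid, basophil and eosinophil, and dendritic cell. A score is the mean log2 CPM over the members of a list, and a response score is the difference between LPS and control. Response scores were compared between study groups by permuting animals over groups. Correlations across animals used two-sided permutation tests with 100000 resamples, or all orderings where fewer than 10 animals entered, and Benjamini-Hochberg adjustment over 3 correlations. Tests, lists, named genes and most alternatives were fixed before the data were examined. A list of heat shock genes was added after.

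Named genes followed a fixed rule. For the LPS response these were the 10 with the largest rise and the 10 with the largest fall among genes with an adjusted p under 0.05, a mean log2 CPM of at least 3 and the same direction in at least 9 of 10 pairs. In each pathway list the 3 tested members with the lowest p were added, and in each cell type list the 2 lowest. For each comparison of study groups the 5 genes with the lowest p were named. Some genes that the rule names are not reported here.

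The steps were tested on simulated counts with known changes. For the LPS response 94.6% of 1.5-fold changes and 100% of 2-fold and 4-fold changes were recovered among 11230 genes, with 2.5% false calls. For the response across study groups 3.51%, 13.7% and 78.6% were recovered among 11233 genes, with 4.29% false calls. Changes between study groups were placed in a single group. In these tests of the response the spread added per animal was shared by its control and LPS libraries. The simulated response thus did not vary between animals beyond count noise, so these rates may not carry over to responses that vary between animals. For the control libraries the first simulation, which gave animals an added log-normal spread with an SD of 0.3, recovered 0.763%, 11.9% and 84.5%, with 10.4% false calls, above the nominal level. For the LPS libraries it recovered 2.47%, 12.5% and 81.7%, with 9.52% false calls. A simulation without that spread was added after this excess was seen, and gave 6.62% false calls for the control and 3.95% for the LPS libraries. By limma-voom the first simulation gave 4.28% and 4.41% false calls. The list tests called 3 of 3 changed lists, with every member shifted 2-fold, and 0 of 20 unchanged ones. Genes were simulated without correlation between them, against estimates of 0.34 to 0.58 in the lists called in the data. The simulation therefore does not show how the list tests perform at such correlations.

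Alternatives covered other scaling factors, other filters, DESeq2, limma-voom, no block for the animal, sample date as a covariate or alone, the deposited residuals, and leaving out animals or study groups. Total counts of 6169950 to 17405800 per library set the precision for genes with few reads.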

Results

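Whole blood of 44 female rhesus macaques was sequenced after 4 h with LPS, a bacterial cell wall component that activates innate immune cells, or with medium alone. The count table held 83 libraries, 43 control and 40 LPS, and 39 animals had both. The animals belonged to 9 study groups of 4 or 5 animals, sampled on 6 dates. Total counts ran from 6169950 to 17405800 per library, with a median of 10962400 in control and 9547210 in LPS libraries. HBB, which encodes beta globin, took 2.17% to 61.1% of the counts of a library. HSPA1A, an inducible heat shock chaperone, took 0.00240% to 8.81%. Dominance rank, which the title of the series implies as the variable of interest, was not analysed here because the labels do not give it.

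The first comparison asked which transcripts changed with LPS within the same animal. Most of the cytokine, chemokine and NF-kB pathway transcripts tested rose with LPS. IL1A, which encodes the cytokine interleukin 1 alpha, rose by 9.71 ± 0.25 on the log2 scale (SE, n = 39 pairs), from 0.266 ± 0.273 to 254 ± 326 CPM (SD), and was higher in 39 of 39 pairs. IL6 rose by 6.95 ± 0.39, from 0.379 ± 0.315 to 113 ± 288 CPM, and TNF by 3.74 ± 0.19. The chemokine CCL20 rose by 8.85 ± 0.30, from 0.359 ± 0.677 to 172 ± 284 CPM. Control values of IL1A, IL6 and CCL20 rest on few reads, so the size of these log2 rises is uncertain. NFKBIA, the inhibitor that NF-kB itself induces, rose 19.2-fold, from 142 ± 65.4 to 2972 ± 1858 CPM. Transcripts that fell included CSF1R, the receptor of the monocyte growth factor CSF1, which fell by 1.54 ± 0.16 from 156 ± 95.4 to 49.2 ± 24.2 CPM.

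Among the 10 named rises, GPR84, a receptor for medium-chain fatty acids, rose by 6.90 ± 0.46 (log2 ± SE). PTX3, a secreted pattern recognition protein, rose by 6.50 ± 0.28 and was higher in 39 of 39 pairs. IL1RN, the interleukin 1 receptor antagonist, rose by 5.31 ± 0.33. IL1B rose by 4.59 ± 0.31, CXCL3 by 4.63 ± 0.40 and CCL3L3 by 4.95 ± 0.25. CCL3L3 belongs to a family of near-identical copies, so its value is uncertain. IER3, MARCKS and the adhesion molecule ICAM1 rose by 4.58 ± 0.26, 4.53 ± 0.32 and 4.29 ± 0.26. Among the 10 named falls, SOWAHD fell by 2.20 ± 0.19 and was lower in 39 of 39 pairs. TLR8, a receptor for single-stranded RNA, fell by 2.15 ± 0.22. TGFBI, TMEM170B and IGFBP4 fell by 1.81 ± 0.19, 1.75 ± 0.16 and 1.62 ± 0.17. The scavenger receptor LRP1 fell by 1.37 ± 0.15. NACC2, PDK4 and MYOF fell by 1.30 ± 0.17, 1.27 ± 0.18 and 1.26 ± 0.12.

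**Figure D1:**
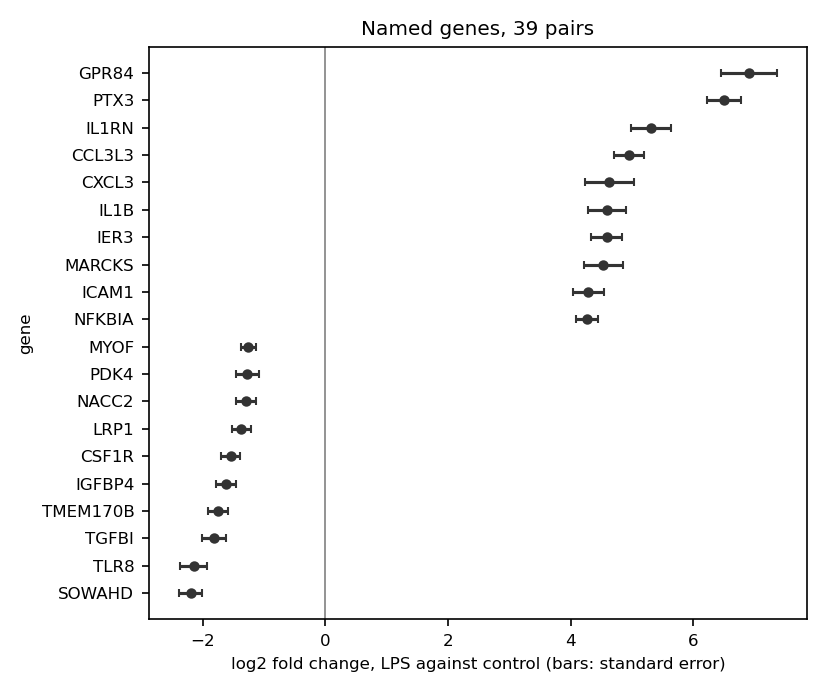
Log2 fold change of LPS against control (x axis) for the 20 named genes (y axis) over 39 pairs, with bars for the standard error. GPR84 has the highest value, 6.90, and SOWAHD the lowest, -2.20.

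Of 11262 tested genes, 4099 changed at an adjusted p under 0.05 by edgeR's quasi-likelihood test with the animal as a block, 1859 higher and 2240 lower. With at least 2-fold change the count was 412 genes, 326 higher and 86 lower. The share of higher calls was 45.4%. It was 48.4% with RLE factors, 48.6% by DESeq2, 45.2% by limma-voom and 43.4% with the residuals. With upper quartile factors it was 35.2% (1521 higher, 2805 lower). Without the block for the animal the count of changed genes was 1819.

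The inflammatory cytokine list rose as a group: 14 of 15 tested members rose and 1 did not pass, with the same 14 when adjusted over the list alone (adjusted p = 0.00439 with an estimated correlation). Of 12 chemokines 10 rose and 2 did not pass, 10 when adjusted over the list alone (adjusted p = 0.00439 with an estimated correlation). CCL4 rose by 4.21 ± 0.22 and CXCL6 by 5.02 ± 0.28 (log2 ± SE). All 19 tested members of the NF-kB list rose, 19 when adjusted over the list alone (adjusted p = 0.00666 with an estimated correlation). TNFAIP3, a feedback inhibitor of NF-kB, rose by 3.30 ± 0.17 and NFKBIZ by 2.58 ± 0.15.

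Of 32 interferon-stimulated genes 21 rose and 11 did not pass, 21 when adjusted over the list alone (adjusted p = 0.455 with an estimated correlation). DHX58, IFIH1 and ISG15 rose by 1.40 ± 0.18, 1.46 ± 0.19 and 1.59 ± 0.28. In the TLR4 list 8 of 18 members rose, 2 fell and 8 did not pass, with 8 rises and 3 falls when adjusted over the list alone (adjusted p = 0.0937 with an estimated correlation). The TLR4 co-receptor CD14 rose by 2.02 ± 0.18, the adaptor TICAM1 by 1.75 ± 0.14 and the kinase IKBKE by 0.54 ± 0.07. In the immediate early list 9 of 15 members rose and 3 fell, with the same 9 and 3 when adjusted over the list alone (adjusted p = 0.139 with an estimated correlation), among them JUNB with a rise of 1.20 ± 0.11 and MAFF with 1.14 ± 0.10. In the inflammasome list 4 of 10 members rose and 2 fell, with 4 and 3 when adjusted over the list alone (adjusted p = 0.681 with an estimated correlation). NLRP3, an inflammasome sensor, rose by 1.39 ± 0.16 and PANX1 by 1.09 ± 0.16, while the adaptor PYCARD fell by 0.76 ± 0.09. The mean of the inflammasome list was 0.16 and its median -0.04 (log2), and its test pointed upwards.

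In the glucocorticoid-responsive list 5 of 16 members rose and 4 fell, the same when adjusted over the list alone (adjusted p = 0.455 with an estimated correlation). IL1R2, a decoy receptor, rose by 2.28 ± 0.18 and the scavenger receptor CD163 fell by 1.47 ± 0.21. The mean of this list was 0.34 and its median -0.00 (log2), and its test pointed upwards. In the glycolysis list 4 of 19 members rose and 6 fell, with 4 and 7 when adjusted over the list alone (adjusted p = 0.681 with an estimated correlation). HK2 fell by 1.26 ± 0.13 and PGAM1 by 0.34 ± 0.08, while PFKFB3 rose by 0.67 ± 0.10. In the oxidative phosphorylation list 1 of 24 members rose and 11 fell, with 1 and 12 when adjusted over the list alone (adjusted p = 0.499 with an estimated correlation). ATP5A1, ATP5C1 and NDUFV1 fell by 0.35 ± 0.07, 0.35 ± 0.08 and 0.23 ± 0.05. In the MHC class II list 2 of 17 members rose and 4 fell, the same when adjusted over the list alone (adjusted p = 0.707 with an estimated correlation), with falls of 0.48 ± 0.08 in MAMU-DMA, 0.45 ± 0.09 in CIITA and 0.68 ± 0.13 in CD86. In the MHC class I list 4 of 13 members rose, 4 when adjusted over the list alone (adjusted p = 0.642 with an estimated correlation), among them TAP1 by 0.53 ± 0.07, TAPBP by 0.70 ± 0.09 and PSME2 by 0.72 ± 0.10. Of 13 phagocyte receptors 3 rose, FPR2 by 3.18 ± 0.24, C3AR1 by 2.61 ± 0.22 and FPR1 by 1.96 ± 0.17, and 4 fell, the same when adjusted over the list alone (adjusted p = 0.987 with an estimated correlation). The mean of the phagocyte list was 0.02 and its median -0.09 (log2), and its test pointed downwards. None of 28 ribosomal protein genes passed, 0 when adjusted over the list alone (adjusted p = 0.867 with an estimated correlation). RPL4, with the lowest p among them, stood at -0.21 ± 0.10 (adjusted p = 0.0933 by edgeR), and it passed with upper quartile factors (adjusted p = 0.0416), without Jl11_SGE2, without Pp10_SGE2 and with the heat shock score as a covariate.

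Markers of blood cell types moved in both directions. Of 15 monocyte markers 4 rose and 8 fell (adjusted p = 0.681 with an estimated correlation), with CD14 among the rises and CSF1R among the falls. Of 15 neutrophil markers 6 rose, among them LTF by 0.80 ± 0.11 and PGLYRP1 by 0.80 ± 0.12, and 1 fell (adjusted p = 0.681 with an estimated correlation). Of 12 B cell markers 4 fell (adjusted p = 0.707 with an estimated correlation). The complement receptor CR2 fell by 0.31 ± 0.08 and FCRLA fell by 0.30 ± 0.09, which did not pass with all libraries and the animal as a random effect. Of 16 T cell markers 5 fell (adjusted p = 0.681 with an estimated correlation), among them CD27 and CD4, which both fell by 0.32 ± 0.08. Of 17 cytotoxic and NK markers 6 fell (adjusted p = 0.642 with an estimated correlation). The NK cell adhesion molecule NCAM1 fell by 0.80 ± 0.15 and the pore-forming protein PRF1 fell by 0.66 ± 0.16.

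Of 7 basophil and eosinophil markers 4 fell, 5 when adjusted over the list alone (adjusted p = 0.139 with an estimated correlation). IL5RA, the interleukin 5 receptor chain, fell by 0.97 ± 0.22 and was lower in 31 of 39 pairs, and CCR3 fell by 0.58 ± 0.15 and was lower in 27. Of 5 dendritic cell markers 2 fell and 1 rose (adjusted p = 0.681 with an estimated correlation). FCER1A, the high-affinity IgE receptor chain, fell by 1.96 ± 0.20 and the transcription factor BATF3 rose by 1.33 ± 0.19. None of 11 platelet markers passed (adjusted p = 0.987 with an estimated correlation), with TREML1 at 0.48 ± 0.20 (adjusted p = 0.0514 by edgeR) and a list mean of 0.01 against a median of -0.00 (log2). TREML1 passed by DESeq2, with RLE factors, with the residuals by limma, with all libraries and the animal as a random effect, and with Aa11_SGE2, Cw10_SGE2, VBB_SGE2 or Ze12_SGE2 left out. None of 9 erythroid markers passed (adjusted p = 0.777 with an estimated correlation). For the cell type lists other than basophils and eosinophils, the counts adjusted over the list alone were the same. Within single sample dates, with fewer pairs, the direction of ATP5C1, PFKFB3, TAPBP, PSME2, CD4 and IL5RA turned on 1 date each.

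Of the 23 lists, 3 were called with an estimated correlation and 9 with a preset correlation of 0.01. By fry, which tests whether the members of a list move on balance one way, 16 were called.

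**Figure D2:**
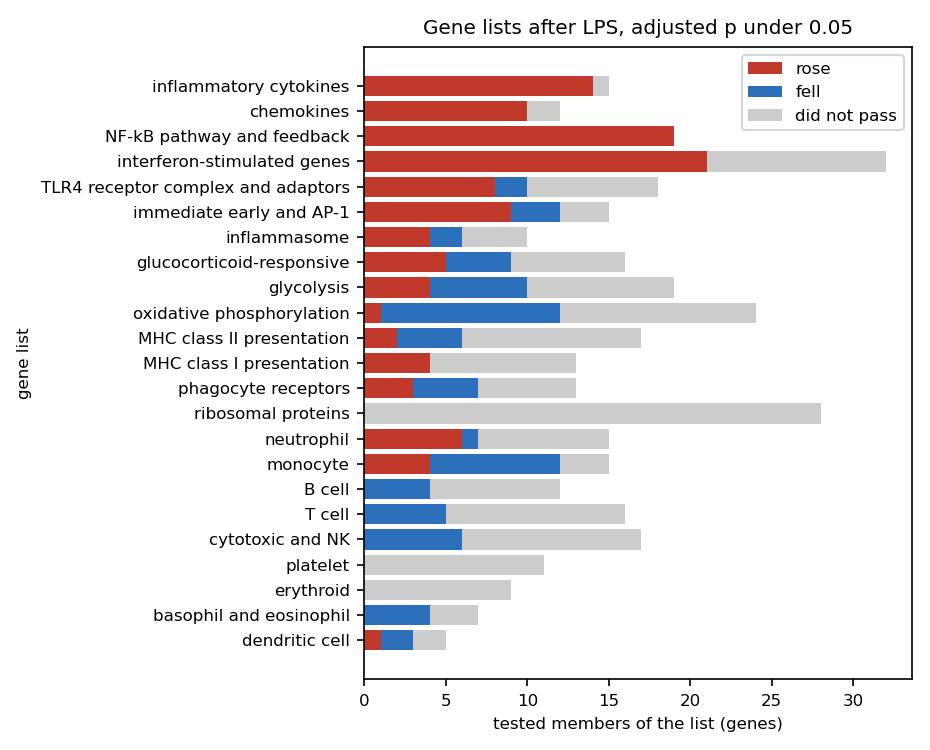
Number of tested genes (x axis) that rose, fell or did not pass at an adjusted p under 0.05 in each of the 23 gene lists (y axis), over 39 pairs. All 19 NF-kB members rose, and none of the 28 ribosomal protein genes passed.

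The second comparison asked whether unstimulated blood differed between study groups. In the control libraries 51 of 12392 genes differed by edgeR's quasi-likelihood F test. TTC14 was highest in Pp10_SGE2, at 7.21 ± 0.55 log2 CPM (SD, n = 5), against 5.38 ± 0.28 in Fq9_SGE2 (n = 5). ZNF473 and BCOR, a transcriptional corepressor, were lowest in Pp10_SGE2, at 3.71 ± 0.34 and 5.12 ± 0.57 log2 CPM. HSD3B7, an enzyme of bile acid synthesis, was highest in Ze12_SGE2, at 3.03 ± 2.42 log2 CPM (n = 4). PRKD1, a protein kinase, was highest in Jl11_SGE2, at 1.21 ± 2.76 log2 CPM. For HSD3B7 and PRKD1 this SD exceeded the distance to the next group, and adjusted p of the 5 genes ran from 0.00123 to 0.0173. The count was 20 by limma-voom and 2 with the sample date as a covariate. Without RVb12 and RIa13 of Pp10_SGE2, whose control libraries had platelet marker scores of 1.24 and 1.22 log2 CPM against 3.06 to 8.13 in the other animals, it was 5, and TTC14, ZNF473 and BCOR did not pass. With the sample date as a covariate, ZNF473 was the 1 gene of these 5 that passed. The fit with the date tested fewer contrasts than the main one. By control library dates Pp10_SGE2 could be compared with Aa11_SGE2 alone, and Bc8_SGE2 with no group.

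The third comparison asked the same of stimulated blood. In the LPS libraries 1514 of 12318 genes differed between study groups. OAS2, an antiviral enzyme, stood at 8.80 ± 1.85 log2 CPM in Jl11_SGE2 (SD, n = 5) and between 5.01 and 6.03 in the other groups. IFIT5 stood at 7.09 ± 2.37 in Jl11_SGE2 and between 3.40 and 4.41 elsewhere. OAS1, PML and the RNA sensor DDX58 were also highest in Jl11_SGE2, at 5.54 ± 1.15, 7.10 ± 1.42 and 8.54 ± 1.98 log2 CPM. Adjusted p for these 5 genes ran from 5.13e-06 to 9.65e-06 by edgeR. Without Jl11_SGE2 the count was 187 genes, and without Pp10_SGE2 it was 400.

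The fourth comparison tested the response itself: 237 of 11262 genes changed with LPS by different amounts between study groups. GPR65, a proton-sensing receptor, changed by -0.09 ± 0.79 in Pp10_SGE2 (log2, SD, n = 5) and by 3.37 ± 0.88 in Jl11_SGE2 (n = 5), with the other groups between 2.04 and 2.70. CD274, which encodes PD-L1, changed by 0.09 ± 0.98 in Pp10_SGE2 and 4.95 ± 1.28 in Jl11_SGE2. IDO1, an enzyme of tryptophan breakdown, changed by -0.25 ± 0.47 and 3.31 ± 1.26, and APOBEC3A, a cytidine deaminase, by -0.50 ± 0.97 and 5.43 ± 1.06 in the same groups. SLC2A6, a glucose transporter family member, changed by -0.31 ± 0.51 in Pp10_SGE2 and by 1.37 to 2.47 in the other groups. Pp10_SGE2 includes RVb12, whose LPS library showed almost no LPS response. Over its other 4 animals the changes were 0.18 in GPR65, 0.37 in CD274, -0.10 in IDO1, -0.32 in APOBEC3A and -0.49 in SLC2A6, and over the 3 without RIa13 as well 0.38, 0.66, 0.03, -0.05 and -0.32. The platelet list changed by 1.52 in Pp10_SGE2 against -0.64 to 0.53 in the other groups, but this difference did not pass (adjusted permutation p = 0.131). Its score went from 1.24 to 5.27 log2 CPM in RVb12 and from 1.22 to 3.35 in RIa13. In RIe12, RPp10 and RWu12 it went from 6.75 to 7.24, 6.77 to 7.77 and 6.25 to 6.18. Adjusted p of GPR65, CD274, IDO1, APOBEC3A and SLC2A6 ran from 0.000104 to 0.000159 by edgeR. For 125 of the 237 genes the group farthest from the mean was Pp10_SGE2, with a response below it, and for 71 it was Jl11_SGE2, with a response above it.

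Among gene lists, the response differed between study groups for 6 of 23 lists by a permutation test of animals over groups. The inflammatory cytokine response was 5.00 ± 1.12 (log2, SD) in the 5 animals of Jl11_SGE2 and 1.20 ± 0.93 in the 5 of Pp10_SGE2. The interferon-stimulated response was 2.88 ± 1.60 in Jl11_SGE2 and -0.14 ± 0.25 in Pp10_SGE2, and between 0.25 and 0.54 in the other groups. Without RVb12 the means of Pp10_SGE2 were 1.40 and -0.07 (n = 4), and without RIa13 as well 1.37 and 0.04 (n = 3). Of the 32 tested interferon-stimulated genes 21 were among the 237 genes. Chemokines, the NF-kB list, the TLR4 list and the MHC class I list also differed. A heat shock score, chosen after the data were seen, was lowest in the LPS libraries of the same groups, at 6.93 ± 2.65 log2 CPM in Jl11_SGE2 and 8.46 ± 1.47 in Pp10_SGE2, with means of 8.76 to 10.71 in the others. The count of 237 became 54 without RVb12 and RIa13, 22 without Pp10_SGE2, 115 without Jl11_SGE2, and 23 without the block for the animal. Study group and sample date overlapped. Only Bc8_SGE2 was sampled on 25 November 2014, so a fit with the date cannot separate that group from that date. Such a fit tests fewer contrasts between groups. With date by treatment as a covariate 189 genes passed, and within 13 December 2014 alone 283 did. Without RJI11, the 1 animal of Jl11_SGE2 on that date, 0 did by edgeR, with 1180 at an unadjusted p under 0.05.

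**Figure D3:**
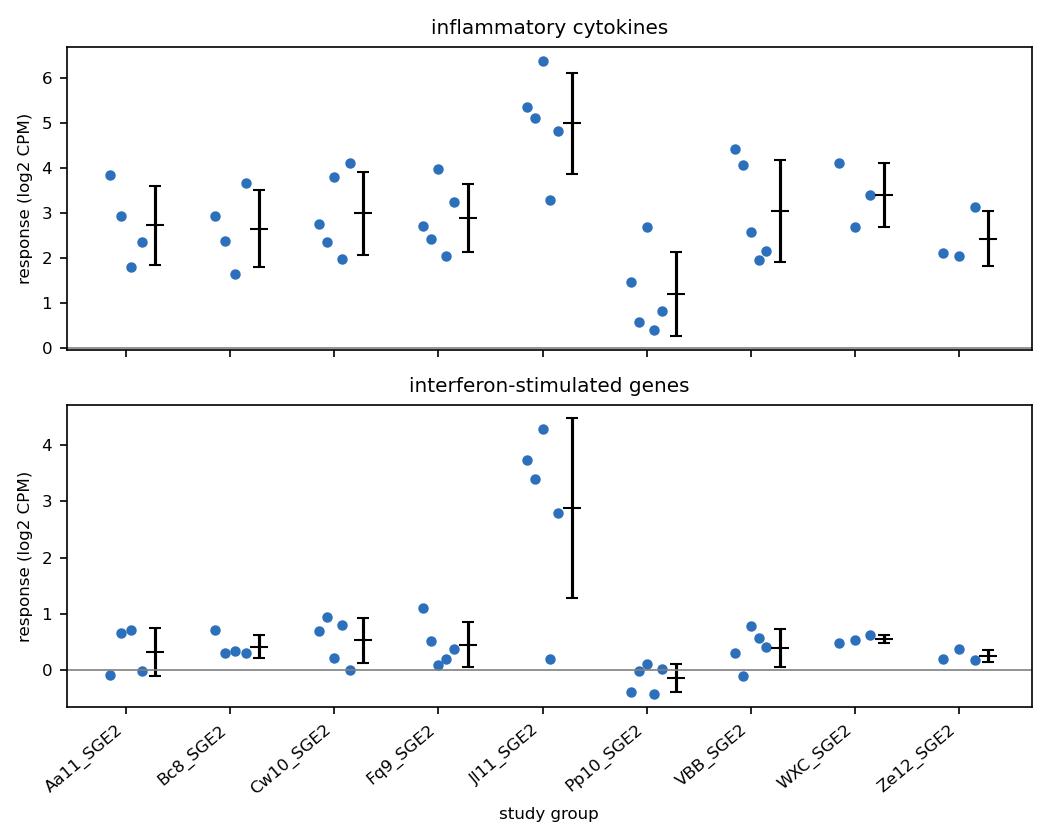
Response of each animal (points, LPS minus control, mean log2 CPM over the list, y axis) by study group (x axis), with the group mean and SD beside the points, for inflammatory cytokines (top) and interferon-stimulated genes (bottom). In the lower panel 4 of the 5 Jl11_SGE2 animals lie between 2.79 and 4.29, and no animal of another group lies above 1.09.

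The last comparisons asked which measures varied together across the 39 animals, in a family of 3 correlations. Animals with more monocyte marker transcripts in the control library had a larger inflammatory cytokine response, with Pearson r = 0.37 (permutation p = 0.0215, adjusted p = 0.0322) and Spearman rho = 0.44 (permutation p = 0.00508, adjusted p = 0.0152). Without RPp10 and RWu12 of Pp10_SGE2, the animals farthest from the median, r was 0.31 and no longer passed (adjusted p = 0.0631), while rho was 0.41 and passed (adjusted p = 0.0189). Without Jl11_SGE2 r was 0.44 (adjusted p = 0.0145) and rho 0.52 (adjusted p = 0.0033), and without RVb12 and RIa13 r was 0.47 (adjusted p = 0.0052) and rho 0.55 (adjusted p = 0.0019). Within 20 November 2014 r was 0.15 (n = 9, exact p = 0.687), and within 13 December 2014 it was 0.57 (n = 12, permutation p = 0.0592) with rho = 0.79 (permutation p = 0.0034, adjusted p = 0.0102). By the date of the LPS library no other date held 6 animals. By the date of the control library, which differs for 3 animals, r was 0.19 within 20 November 2014 (n = 9, exact p = 0.612) and 0.75 within 12 January 2015 (n = 7, exact p = 0.0673). As deviations from the date means, r was 0.33 (adjusted p = 0.0594) and rho 0.33 (adjusted p = 0.108), and neither passed. No setting of the 3 correlations adjusted for study group, although the cytokine response differed between groups. A relation within study groups was therefore not tested.

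The glucocorticoid-responsive list of the control library and the cytokine response gave r = 0.25 (permutation p = 0.122, adjusted p = 0.122) and rho = 0.36 (permutation p = 0.0253, adjusted p = 0.0380). Without RIa13 and RNi12, the animals farthest from the median, r was 0.41 (adjusted p = 0.0180). Without Jl11_SGE2 r was 0.52 (adjusted p = 0.0054) and rho 0.51 (adjusted p = 0.0033). The call by rho was lost with RLE factors (rho = 0.31, adjusted p = 0.0585), with the median of the members (rho = 0.19, adjusted p = 0.366), with deviations from the date means (rho = 0.24, adjusted p = 0.137) and without RVb12 and RIa13 (rho = 0.31, adjusted p = 0.0934). Within 20 November 2014 r was 0.32 (n = 9, exact p = 0.409), and within 13 December 2014 it was 0.53 (n = 12, permutation p = 0.0793). The interferon response fell into separate clusters, with 4 animals of Jl11_SGE2 at 2.79 or above and the other 35 at 1.09 or below, so its relation to the cytokine response is given without Jl11_SGE2. Over those 34 animals r was 0.12 (permutation p = 0.488) and rho 0.03 (permutation p = 0.864). Within 12 January 2015 by control library date r was -0.75 (n = 7, exact p = 0.0659).

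**Figure D4:**
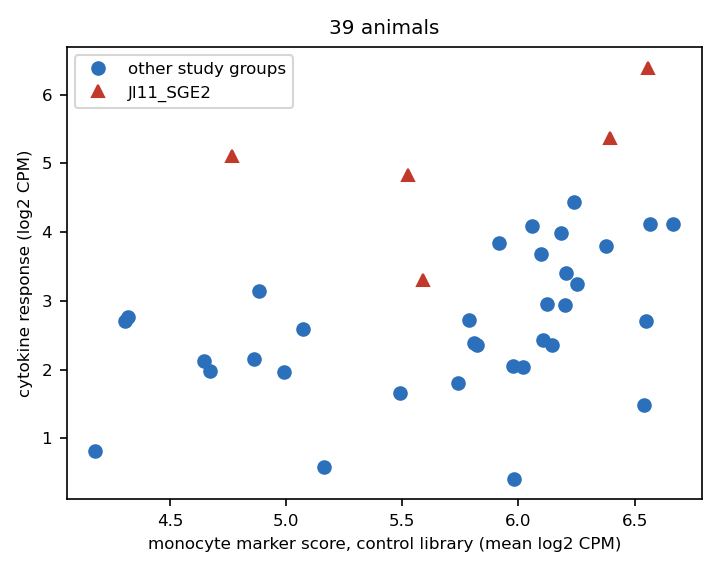
Inflammatory cytokine response (y axis, log2 CPM) against the monocyte marker score of the control library (x axis, mean log2 CPM) for 39 animals, with Jl11_SGE2 as triangles. Pearson r over all animals is 0.37.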

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

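The tests of heat shock transcripts, of sample date and of monocytes as the whole cause were chosen only after the results were seen, while the test of the monocyte difference and the splits were set before.

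The response to LPS differed between study groups for 237 genes by the interaction test of edgeR. By limma-voom 316 genes passed, and 1 of 100 splits, the real one, gave as many, with 67 as the highest of the others. This argues against chance, though 100 splits cannot show a share under 1 in 100. They also dealt animals to groups without regard to sample date. Among lists, adjusted permutation p was 0.000805 for chemokines and 0.000805 for the NF-kB list. It was 0.00192 for inflammatory cytokines, 0.00328 for interferon-stimulated genes, 0.00465 for the TLR4 list and 0.0468 for the MHC class I list. Single animals moved the limma-voom count by more than 1.5 times: it was 187 without RPq11, 190 without RIa13, 198 without RVb12 and 210 without RJI11.

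In Bc8_SGE2 the interferon response of RCy13 was 0.713, apart from the next animal at 0.338. It was the 1 value found in 28 such checks, and chance alone gives about 1 in 20.

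Interferon-stimulated genes rose more after LPS in Jl11_SGE2 than in the other groups, by 2.55 ± 0.72 on the log2 scale. The SE and the 95% interval of 0.56 to 4.53 used separate variances. Jl11_SGE2 was picked among 9 groups for this high response in the same data. The intervals and exact p for its interferon response, here and below, leave that choice out and are too strong. A larger share of monocytes is argued against as the whole cause only if the response rises in proportion to their score. That proportion was assumed and not estimated. With the score subtracted in each animal the difference was 2.48 ± 0.69 (95% interval 0.63 to 4.34, exact p = 5.2e-05). As the score itself differed by 0.0619, the subtraction could change little. Low heat shock transcripts stay open. With the scores of both libraries in the model the difference was 2.22 with a 95% interval of 1.57 to 2.86, but -0.24 to 4.67 with unequal variances. With the score as a covariate 20 of 32 interferon-stimulated genes differed between study groups, against 21 without it. In the 34 other animals Spearman rho between the score of the LPS library and the interferon response was -0.0530 (permutation p = 0.768, 95% bootstrap interval -0.409 to 0.304). It was 0.383 within 20 November 2014 (n = 9, exact p = 0.313) and -0.627 within 13 December 2014 (n = 11, permutation p = 0.0440). Within Jl11_SGE2 the animals with a response of 2.79 or more had LPS library scores of 4.58, 4.78, 6.97 and 7.18. RRr13, with a score of 11.1, responded by 0.19. In other groups RIa13, RAc8 and RQp9 had scores of 6.68, 6.76 and 7.07 and responded by -0.40, 0.31 and 0.80. No score in those groups was lower than 6.68. Sample date stays open too: by the dates of the LPS libraries exact p was 0.00417 among 21 animals that shared a date across groups, but on 11 November 2014 this rests on RJs11 and RJj10, whose control libraries carry other dates, and by control dates 3 of the 5 Jl11_SGE2 animals shared no date with another group (exact p = 0.0417 for the other 2, among 16 animals, of which RJI11 alone was high). A part played by monocytes was not excluded, as their score differed by 0.0619 with an SE of 0.347 (exact p = 0.863), and a difference between the study groups themselves may underlie the pattern and was not tested.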

How the results depend on the processing

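The alternatives that leave out RVb12 and RIa13, Jl11_SGE2 or Pp10_SGE2, that use heat shock scores or library weights, that take 13 December 2014 without Jl11_SGE2, or that take the dates of the control libraries were chosen after seeing the data. The cause was not tested for any change below unless one is given.

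The count of LPS response genes stayed within 1.5 times of 4099 under 20 alternatives. Without the block for the animal, which the pairing calls for, it was 1819. Single dates hold fewer animals. Within them the count was 637 on 11 November, 21 on 20 November, 254 on 25 November and 228 on 3 December 2014. It was 1719 on 13 December 2014 and 203 on 12 January 2015. These counts did not follow the number of pairs. The fit of 20 November held 5 pairs of Pp10_SGE2 and 3 of Aa11_SGE2, and that of 11 November 3 of Jl11_SGE2. The count at 2-fold was 18 on 20 November, 249 on 25 November, 210 on 3 December and 192 on 12 January. Within single dates 6 named genes changed direction. On 11 November ATP5C1 was at 0.16 and IL5RA at 0.0087, on 20 November TAPBP at -0.077 and PSME2 at -0.039, and on 3 December PFKFB3 at -0.095 and CD4 at 0.095 (log2).

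The 51 genes of the control libraries became 31 with RLE factors, 24 without a filter, 1537 by DESeq2, 20 by limma-voom and 2165 with library weights. With sample date as a covariate, which tests fewer contrasts between groups, 2 passed, PLOD3 and ZNF473. With the heat shock score 2 passed, CYP1B1 and HSD3B7. On 13 December alone 1 passed, HAS1, and without Jl11_SGE2 on that date 0 by edgeR, with 901 at an unadjusted p under 0.05. Without the 3 animals with 2 dates 104 passed. Without RVb12 and RIa13 5 passed, DOK2, GLCE, HSD3B7, IL1B and PRKD1. Without Jl11_SGE2 24 passed, and without Pp10_SGE2 2, HSD3B7 and PRKD1. These genes were chosen after their values were seen. The residuals, from which group means are nearly absent, gave 5, GBP3, GPR162, MAP3K8, NFKB1 and SLC11A2. Leaving out 1 animal gave 0 to 401 genes by limma-voom, and 34 of 43 animals moved the count by more than 1.5 times, with 0 without RVb12 (2231 at an unadjusted p under 0.05) and 401 without RRr13.

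The 1514 genes of the LPS libraries became 3452 by DESeq2, 5253 with library weights, 339 on 13 December alone, 15 on that date without Jl11_SGE2, 935 without RVb12 and RIa13, 187 without Jl11_SGE2, 400 without Pp10_SGE2, and 0 with the residuals by limma (24 at an unadjusted p under 0.05). Leaving out 1 animal gave 480 to 2985: 480 without RJI11, 588 without RNi12, 655 without RPq11, 703 without RVe12, 861 without RWu12, 959 without R482 and 2985 without RRr13.

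The 237 genes of the response became 615 by DESeq2, 1135 with library weights, 437 with the heat shock score by treatment, 23 without the block for the animal, 54 without RVb12 and RIa13, 115 without Jl11_SGE2 and 22 without Pp10_SGE2. On 13 December alone it was 283, and without RJI11, the 1 animal of Jl11_SGE2 on that date, it was 0 by edgeR, with 1180 at an unadjusted p under 0.05. The residuals gave 285. Leaving out 1 animal gave 187 to 470 by limma-voom.

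Of 23 lists 3 were called with an estimated correlation, 9 with a preset one and 16 by fry. The monocyte and cytokine correlation lost its call with r = 0.33 for deviations from date means, 0.31 without its 2 farthest animals, 0.15 within 20 November and 0.57 within 13 December (where rho = 0.79 passed), and by control library dates 0.19 within 20 November and 0.75 within 12 January 2015 (n = 7). It passed at r = 0.44 without Jl11_SGE2 and 0.47 without RVb12 and RIa13. The glucocorticoid and cytokine correlation passed at r = 0.52 without Jl11_SGE2 and 0.41 without its 2 farthest animals, while its call by rho was lost with RLE factors, the median of members, deviations from date means and without RVb12 and RIa13. The cytokine and interferon relation was at r = 0.12 without Jl11_SGE2, 0.48 within 20 November and 0.54 within 13 December, where RJI11 of Jl11_SGE2 enters and rho was -0.12 (permutation p = 0.718). By control library dates it was at r = 0.36 within 20 November, and it turned to -0.75 within 12 January 2015.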

Other observations

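The exchange, no-LPS and depth tests were chosen only after the results were seen, as were 2 of the 3 versions of the match between animals, added because the first used genes picked on the same pairs. The first version, the neutrophil test and the splits were set before.

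Heat shock transcripts varied widely between libraries. HSPA1A took 0.00240% to 8.81% of the counts and DNAJB1, its co-chaperone, up to 3.09%. The genes that differed between study groups overlapped across tests: 173 genes differed both in the response and in the LPS libraries, against 29.4 for independent lists, and 26 both in the control and in the LPS libraries, against 6.08. Neither pair of lists is independent, as the control and LPS libraries come from the same animals, so larger overlaps need no effect of the study groups. The first overlap also shares its LPS libraries, so 29.4 is no measure of chance for it. Of the 237 response genes 205 were among the genes that changed with LPS, against 86.3 for independent lists, which is no measure of chance either, as both lists come from the same pairs.

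By limma-voom, 1 of 100 splits that exchanged the libraries within pairs gave as many LPS response genes as the real one. This was the real one itself, with 4224 genes against 2371 for the highest other, which argues against chance. For the LPS libraries across study groups 1 of 100 splits, the real one, gave as many, with 1514 genes against 672. This argues against chance too, though 100 splits cannot show a share under 1 in 100. For the control libraries 2 of 100 splits gave as many, with 20 genes against 151. That share is low, but a random split reached several times the real count, so these splits do not exclude chance for the control libraries. They also dealt animals to groups without regard to sample date. What set that split apart was not traced.

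The LPS library of RVb12 showed almost no LPS response, with a mean of 3.64 log2 CPM over the 10 genes with the largest rise, against 5.07 to 12.2 in the other LPS libraries. The next lowest among the paired LPS libraries were also of Pp10_SGE2, RWu12 at 5.07, RIe12 at 5.36, RIa13 at 6.59 and RPp10 at 7.38. An exchange within the pair is argued against, since its control library stood at 3.27, within the 2.68 to 5.39 of the other controls. A tube without LPS would give the value of 3.64 seen, and so would an animal that did not respond, which stays open. The LPS libraries of RWu12 and RIe12 also lay within the range of the controls, though above their own controls at 2.93 and 3.71. A value in that range therefore does not single out RVb12. A library of another animal also stays a candidate explanation. The control library of RVb12 ranked 2 of 39 for its LPS library (Spearman rho = 0.510, against 0.540 for RWu12), while 38 of 38 other pairs matched their own. In the later versions it ranked 2 and 4, with 36 and 35 of 38. RFd12 ranked 3 and 6 in those versions, so such ranks are not particular to RVb12. Over all genes the correlation within the pair was 0.334 in RVb12, and lower in RTf12 (0.203) and RQp9 (0.243). For RVb12 the margins were narrow and the best match changed from RWu12 to RSi10. The test does not say which of its 2 libraries would be out of place.

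Platelet transcripts were low in the control libraries of RVb12 and RIa13, by -4.08 and -4.10 on the log2 scale from the median of the other animals. Neutrophil scores of the same libraries were higher by 1.09 and 1.76. Low depth is argued against by totals of 8381940 and 8985700 counts, within the 6169950 to 17405800 of the other controls. Dilution by neutrophil RNA is argued against because the platelet score minus the bound set by the other cell types was -1.36 or lower in both libraries. Erythroid scores were higher by 2.27 and 3.32. No biological explanation was tested.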
